A study of Ipomoea batatas with 12 samples.

How the data were processed

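The data were RNA-seq libraries of sweetpotato (Ipomoea batatas) storage roots. Per the labels, the wild-type line M1-125 (WT) and a natural mutant of it (MT) were grown in the field, and the flesh and the skin of their storage roots were collected 120 days after planting. Each of the 4 groups, WT flesh, MT flesh, WT skin and MT skin, had 3 libraries, 12 in all. Per the labels' protocols, total RNA was extracted with TRIzol, ribosomal RNA was removed, polyadenylated RNA was enriched on oligo(dT) beads, and NEBNext Ultra libraries were read on an Illumina NovaSeq instrument. Group and replicate number were taken from the sample titles. The series design speaks of biological replicates without saying whether each came from separate plants, so the p-values measure the spread between these samples.

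The deposited table holds raw counts per gene and library, 225111 genes in all, with a gene length, per the file headers. HISAT2 2.0.5, featureCounts and DESeq2 1.40.2 are named in the submitters' processing notes, with no role or order. The genome build, the annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here. All 12 sample columns were matched to a library by name, and no column was left unused. Total counts ran from 8507461 in MT skin replicate 3 to 20276417 in WT flesh replicate 2, and 73826 genes had no count in any library.

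Gene identifiers have the form Ibat.Brg_v3, a number, a letter, G and a running number. They hold 15 numbers and 6 letters, in 90 number-letter blocks, and 8061 genes lie outside these blocks. The number was read here as the chromosome, the letter as the haplotype and the running number as the order along it. This reading is an assumption, since the table gives no coordinates; sweetpotato is a hexaploid whose base chromosome number equals the count of numbers seen. Copies of a gene on several haplotypes can be nearly identical, so how reads were divided among copies is uncertain for any single identifier. Of the gene lengths, 71.5% are multiples of 3, so many gene models are of coding length.

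The deposited counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, which left 80351 genes holding at least 99% of the counts of each library. Libraries were scaled by TMM, all 4 groups were fitted together, and each contrast was tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05. The 5 contrasts were MT against WT in skin, MT against WT in flesh, skin against flesh in WT, skin against flesh in MT, and the interaction, which is the genotype difference in skin minus that in flesh. Levels are given as CPM, counts per 1e6 counts, with TMM scaling, and log2 CPM used a prior count of 2. Overlaps and enrichments were tested with Fisher's exact test; genes, and copies of a gene above all, are not independent, so these p-values are smaller than independent genes would give. Intervals are at the 95% level. The SE given for a gene's log2 fold change is its absolute size divided by the square root of edgeR's F statistic, which is an approximation. A fold against a group with no counts is a lower bound, computed against 3 counts over that group, and bounds and Poisson intervals cover counting error only. In the deepest library 3 counts correspond to 0.13 CPM and in the shallowest to 0.397 CPM.

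The contrasts, the test, the rule for named genes, the gene lists and most alternatives were fixed before the data were examined. The rule takes genes with adjusted p under 0.05, non-overlapping libraries in the compared groups and a mean log2 CPM of at least 1, ranked by log2 fold change. The condition on libraries has no meaning for the interaction, and leaving it out there was decided when the script was written. Because no source used here pairs these identifiers with names, the rule allowed 2 identifiers that rose and 2 that fell per contrast. A table of annotated sweetpotato genes from another assembly (IBA_r1.0) was searched, and 0 of its entries carried these identifiers. The planned lists of anthocyanin, phenylpropanoid, suberin, starch, carotenoid and other genes, the motif search and the test of runs of neighbouring genes by coordinates were therefore not run. Genes lost or gained in the mutant were only counted, as those with a mean under 1 count in the 6 libraries of a genotype and passing the test in both tissues.

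The analyses by identifier number, by tissue class and of genes absent from a group were chosen after the data were examined. A gene was classed as skin-preferring or flesh-preferring where its mean log2 CPM differed by at least 1 between the tissues, averaged over both genotypes. Because a change in MT moves this average, the classes were also taken from the libraries of each line alone. Classes of a single line still share libraries with the genotype contrasts, so noise in those libraries can tie class and change together. For the parts of a chromosome, genes with a mean log2 CPM of at least 2 were ordered by running number within each block, and the split with the least absolute deviation was found from the skin libraries only, with at least 30 genes on each side, then measured in flesh. The permutation test of this step repeats the search in the skin libraries of every arrangement. Sums of CPM over a part left out genes that reached 200 CPM in any library and were taken relative to all other numbered genes.

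Pairs of libraries of a group were compared by a chi-square of their counts over genes with a summed count of at least 20; it ran from 5.82 to 7.81 per gene, no pair was identical, and all libraries were kept as separate replicates. The pipeline was tested on simulated data, with 200 of 80351 genes changed in each contrast except the interaction, which was not simulated. The changed genes were drawn from those with an expected count of at least 20 in the reference group at the mean library size. Recovery of weaker genes was therefore not measured. The pipeline recovered 29% of genes changed 2-fold and 69% of those changed 4-fold for MT against WT in skin, and 35% and 69% in flesh. For skin against flesh it recovered 20% and 62% in WT, and 31% and 67% in MT. Of the 90 to 112 calls per contrast, 3.92% were false for the skin contrast, 7.14% for flesh, 8.89% for the tissue contrast in WT and 6.67% in MT. The same contrasts called 3985 to 40732 genes in the real data, so shares found with 200 changed genes need not hold there. Steps planted on 6 haplotype blocks of 233 to 459 genes were found within 4 genes of their place in all 6. Steps in the real data can be smaller than those planted, so this result does not show how exactly their splits are placed. Alternatives used RLE scaling, library totals alone, other count filters, DESeq2 1.42.0, a surrogate factor from sva 3.50.0, a replicate block, thinned libraries and leaving out each library; their effect is given in the closing section. Figures were drawn with matplotlib 3.10.9.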

Results

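Transcript levels were measured in the flesh and the skin of storage roots from the sweetpotato line M1-125 and its natural mutant, with 3 libraries per group. The title of the series asks about regulators of storage-root skin colour; the labels do not state the colour of either line. Total counts averaged 18.7 M ± 1.54 M (SD, n = 3) in WT flesh, 17.4 M ± 1.33 M in MT flesh, 11.6 M ± 3.01 M in WT skin and 9.76 M ± 1.14 M in MT skin (M, 1e6 counts), so skin was sampled less deeply than flesh. The 10 most abundant genes of each library took 3.02% ± 0.055 of the counts in WT flesh and 3.21% ± 0.0257 in MT flesh, against 6.25% ± 0.115 in WT skin and 5.14% ± 0.0425 in MT skin (SD, n = 3). The first principal component of log2 CPM held 72.3% of the variance and parted skin from flesh, and the second held 5.23% and parted WT from MT. The labels give no sequencing batch or date.

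The comparison of MT with WT in skin addresses the question in the title. The gene Ibat.Brg_v3.12AG004780 fell from 39.2 CPM ± 8.25 in WT skin to 0 counts in all 3 MT skin libraries (SD, n = 3), at least 332-fold lower, and it had 0 counts in all flesh libraries as well. Ibat.Brg_v3.12AG028750 fell 82.3-fold, from 16 CPM ± 1.06 to 0.201 CPM ± 0.178, on 0, 3 and 2 counts in the MT skin libraries, while it stood at 3.52 CPM ± 0.374 in WT flesh and 3.58 CPM ± 0.27 in MT flesh. In the other direction, Ibat.Brg_v3.06DG004730 rose 18.5-fold, from 0.648 CPM ± 0.668 to 14 CPM ± 8.49, with a wide spread between libraries and 19 of its 24 WT skin counts in replicate 2. Ibat.Brg_v3.02FG002200 rose 9.74-fold, from 1.34 CPM ± 0.625 to 13.3 CPM ± 1.43.

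By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 1.4e-05 for 12AG004780 and 1e-06 for 12AG028750, whose log2 fold change was -6.29 (SE 0.43). By the same edgeR test, 06DG004730 had a log2 fold change of 4.28 (SE 0.78, adjusted p = 0.004) and 02FG002200 one of 3.29 (SE 0.43, adjusted p = 0.00032). Of 80351 tested genes, 5502 differed in skin, 2923 higher and 2579 lower in MT. With library totals alone 2429 were higher and 2888 lower, so the balance of directions in skin rests on the scaling. Among those at least 2-fold apart, 923 were higher and 1391 lower. Genes that rose in MT skin were skin-preferring in 41.8% of cases, against 22.3% of the other tested genes (odds ratio 2.51, 95% interval 2.32 to 2.7, Fisher's exact test). A rise in MT skin itself moves a gene towards this class; with classes from the WT libraries alone the odds ratio was 2.06 (1.91 to 2.23). The class of the genes that fell depended on this choice, since flesh-preferring genes had an odds ratio of 1.57 with classes from both lines and of 0.795 with classes from WT. The log2 fold change of 12AG028750 was -5.67 without MT skin replicate 1 and -6.96 without replicate 2, and that of 06DG004730 was 5.61 without WT skin replicate 2. The count of differing genes was 3583 without WT skin replicate 2, the deepest skin library at 15.1 M counts.

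**Figure D1:**
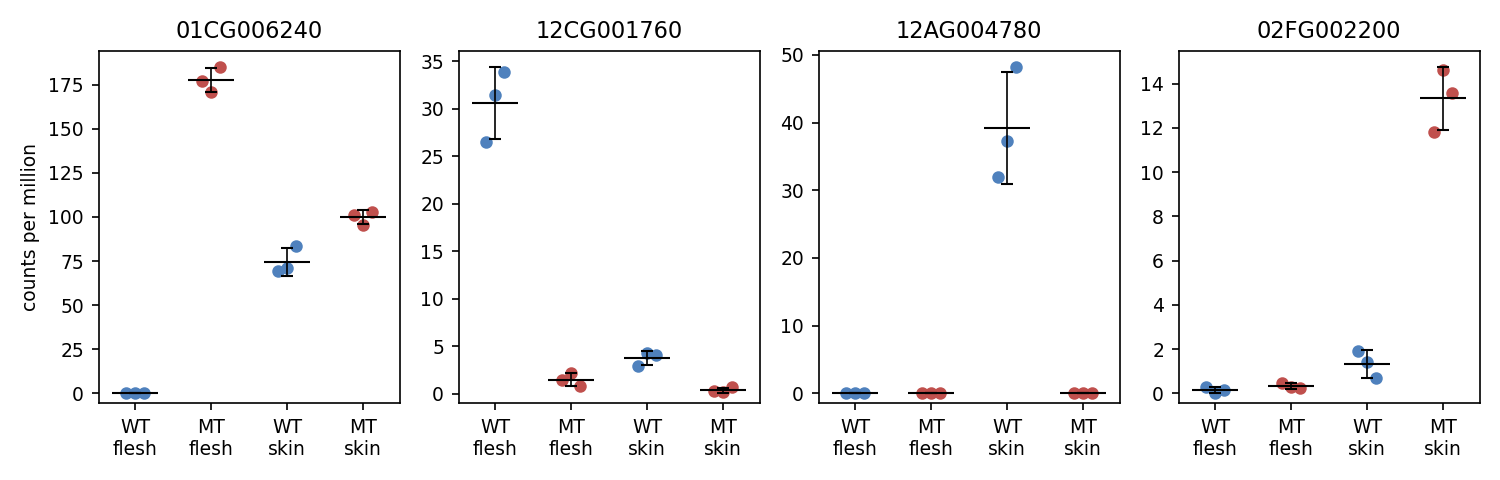
CPM of 4 genes in each library, on linear axes that differ between panels, with blue points for WT, red points for MT, a horizontal line at the mean and bars of 1 SD (n = 3). Gene 01CG006240 is at 0 in WT flesh and at 178 CPM in MT flesh, 12CG001760 falls in the mutant from 30.7 to 1.48 CPM in flesh, 12AG004780 is seen in WT skin libraries and in no others, and 02FG002200 is highest in MT skin.

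In flesh, the mutant carried transcripts that the wild type lacked. Ibat.Brg_v3.01CG006240 had 0 counts in all 3 WT flesh libraries and 178 CPM ± 7.1 in MT flesh (SD, n = 3), at least 3790-fold higher, and it was also present in skin, at 74.5 CPM ± 7.88 in WT and 99.9 CPM ± 3.98 in MT. Ibat.Brg_v3.01EG003800 likewise had 0 counts in WT flesh and 101 CPM ± 8.39 in MT flesh, at least 2150-fold higher. Among genes that fell, Ibat.Brg_v3.12CG001760 went from 30.7 CPM ± 3.8 to 1.48 CPM ± 0.661, 20.4-fold lower, and Ibat.Brg_v3.08AG015460 from 45.8 CPM ± 2.54 to 3.06 CPM ± 0.909, 15.2-fold lower. These last genes were also lower in MT skin, with log2 fold changes of -3.55 and -2.58.

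By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p in flesh was 4.6e-13 for 01CG006240, 2.2e-12 for 01EG003800, 7.4e-07 for 12CG001760 (log2 fold change -4.35, SE 0.33) and 6.2e-08 for 08AG015460 (-3.91, SE 0.24). In all, 3985 genes differed in flesh, 3016 higher and 969 lower in MT, so 75.7% of them were higher. With library totals alone in place of TMM, 2414 were higher and 1708 lower, or 58.6% higher, and that scaling moved the median of all genes by -0.09 on the log2 scale. Skin-preferring genes made up 1615 of the 3016 rises, 53.5% against 21.8% of the other tested genes (odds ratio 4.13, 3.83 to 4.45, Fisher's exact test; 5.35 with classes from WT alone and 2.64 from MT alone). Among the 969 falls 28.4% were skin-preferring, against 23% (odds ratio 1.33, 1.15 to 1.53; 1.03 with classes from WT alone and 1.75 from MT alone). Of these 1615, 136 reached in MT flesh the mean level they had in WT skin. The median rise was 2.21-fold and the median fall 1.74-fold, by fitted values. Genes limited to skin in the wild type stood in MT flesh at a median of 0.059% of their MT skin level (145 genes above 100 CPM in skin of both lines and chosen for low WT flesh).

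A set of 229 genes had at most 3 counts over the 3 WT flesh libraries and was higher in MT flesh by the test. Of these, 182 were above 1 CPM in WT skin. Identifiers numbered 01 made up 38 of the 229 (16.6% against 8.81% of tested genes; odds ratio 2.07, Fisher's exact test, p = 0.00015). Above 10 CPM in MT flesh there were 9 genes, 8 of them numbered 01, spread over all 6 haplotype letters, with running numbers from 3800 to 8920. Some of these 8, which include 01CG006240 and 01EG003800, may be haplotype copies of a single gene, which the identifiers alone cannot show. The reverse, at most 3 counts in MT flesh, held for 47 genes, of which 21 were numbered 12 and 0 were above 10 CPM in WT flesh. Of these 47, 34 were above 1 CPM in WT skin, so presence there was common in both sets. In skin, 87 genes were so absent from WT and 278 from MT, 56 of the latter numbered 12. MT skin libraries averaged 9.76 M counts against 11.6 M in WT skin, which makes absence from MT skin the easier condition.

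**Figure D2:**
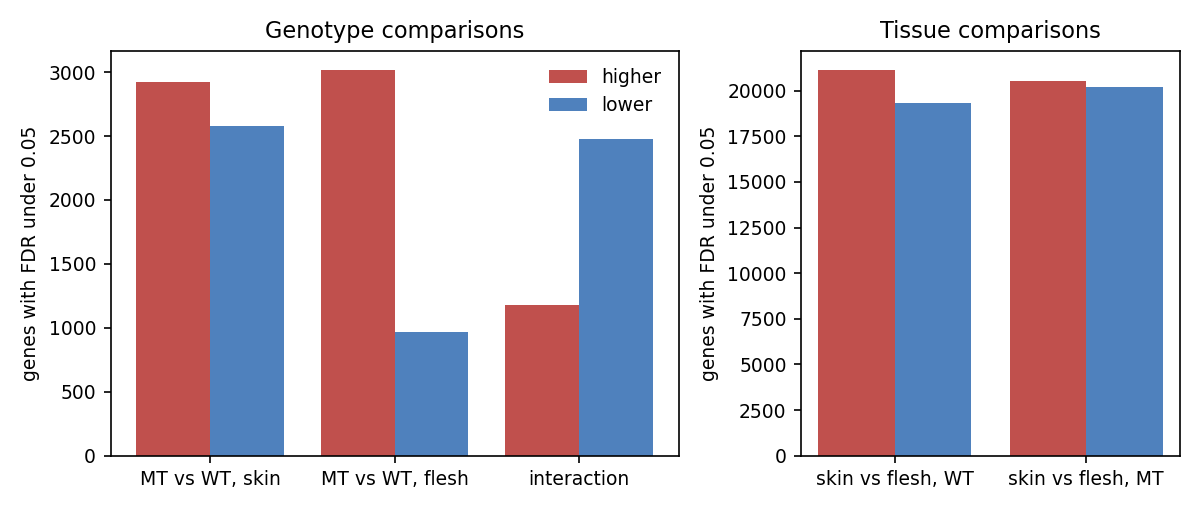
Number of genes with an adjusted p under 0.05 in each comparison, with genes higher in red and lower in blue, for MT against WT and the interaction at left and for skin against flesh at right, where the vertical axis is longer. In flesh 3016 genes are higher and 969 lower in MT, while the other genotype contrast, in skin, has 2923 higher and 2579 lower.

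Genes that differed between the lines in both tissues were more numerous than independent lists would share. There were 887 genes higher in MT in skin and in flesh, where independent lists would share 110, and 189 lower in both, against 31.1 (one-sided Fisher's exact test, p = 4.8e-90 for the lower genes). A further 327 genes differed in both tissues in opposite directions, where independent lists would share 132. Across genes, the genotype difference in skin and in flesh had a correlation of 0.119, and genes are not independent replicates. Of the genes changed in the same direction, 82.4% were higher in MT, and 69.6% with library totals alone. The contrasts share no library, though they share an estimate of the spread.

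The shared changes were concentrated on identifiers numbered 12. Of 6161 tested genes numbered 12, 273 changed the same way in both tissues, or 4.43%, against 1.08% of the 74190 other genes (odds ratio against all others 4.24 with Fisher's exact test, adjusted p = 4.9e-70 over 15 numbers). The other numbers lay between 0.593% and 1.67%. Of the 189 genes lower in both tissues, 94 were numbered 12, which is 49.7% against 7.67% of tested genes. In each tissue alone, 12.7% of genes numbered 12 differed in skin against 6.36% of the others, and 9.01% against 4.62% in flesh.

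**Figure D3:**
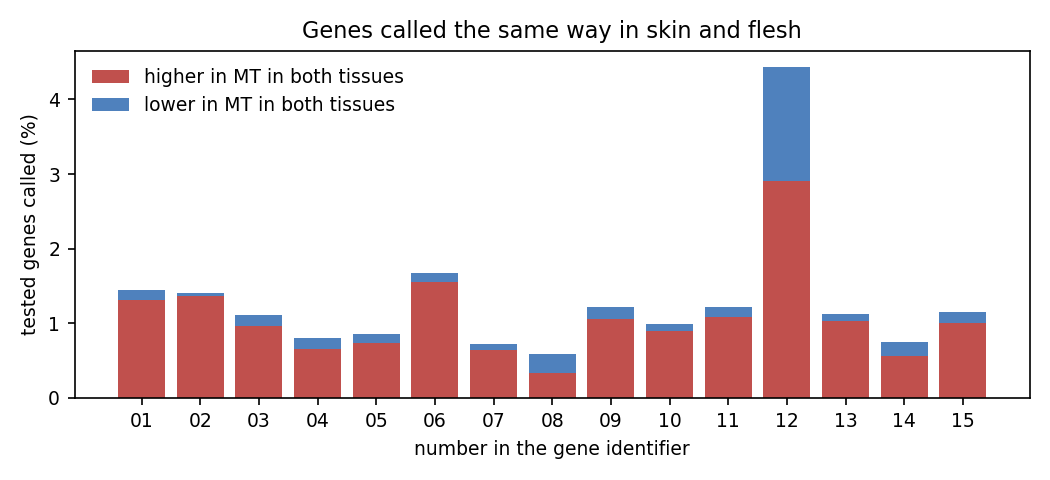
Percent of tested genes that changed in the same direction in skin and in flesh, by the number in the gene identifier, with genes higher in MT in red and lower in blue, stacked from 0. Number 12 stands at 4.43%, and the other numbers lie between 0.593% and 1.67%.

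Along number 12, genes with low running numbers were lower in the mutant on haplotypes A to E. Genes with high running numbers were higher on all 6 haplotypes. With the split of each haplotype found in skin, the median log2 difference of the first part was -0.10 ± 0.011 in skin and -0.05 ± 0.014 in flesh, and that of the second part 0.18 ± 0.006 and 0.17 ± 0.01 (SE, n = 3 against 3; 970 and 1379 genes). In flesh, which played no part in finding the split, the second part exceeded the first by 0.22 ± 0.02, and no other number had a flesh step beyond 0.042 in either direction. Over both tissues the step was 0.25 (two-sided exact permutation test of genotype within tissue with the split searched again in each of 400 arrangements, p = 0.005). Number 12 was picked from 15 numbers after the data were seen; over these, with the splits held fixed, the exact permutation p adjusted by Benjamini-Hochberg was 0.075 for number 12 and for number 06, whose step was 0.027, and 400 arrangements cannot give number 12 a smaller p. Arrangements that mixed genotype in both tissues reached at most 0.148, those that left it whole in skin only 0.19 and those that left it whole in flesh only 0.232. Haplotypes A to E split between running numbers 7270 and 12020; haplotype F split at 25540, and both of its parts were higher in MT. Of the genes lost from MT in both tissues, all 15 were numbered 12, 13 of them in the first part, and 2 genes were gained, 1 of them numbered 12. Within a single tissue, the fall of the first part of number 12 over all haplotypes was close to falls elsewhere. The first part of number 08 stood at -0.095 in skin and the second part of number 14 at -0.045 in flesh. Neither fell in the other tissue, with 0.016 for number 08 in flesh and 0.034 for number 14 in skin.

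**Figure D4:**
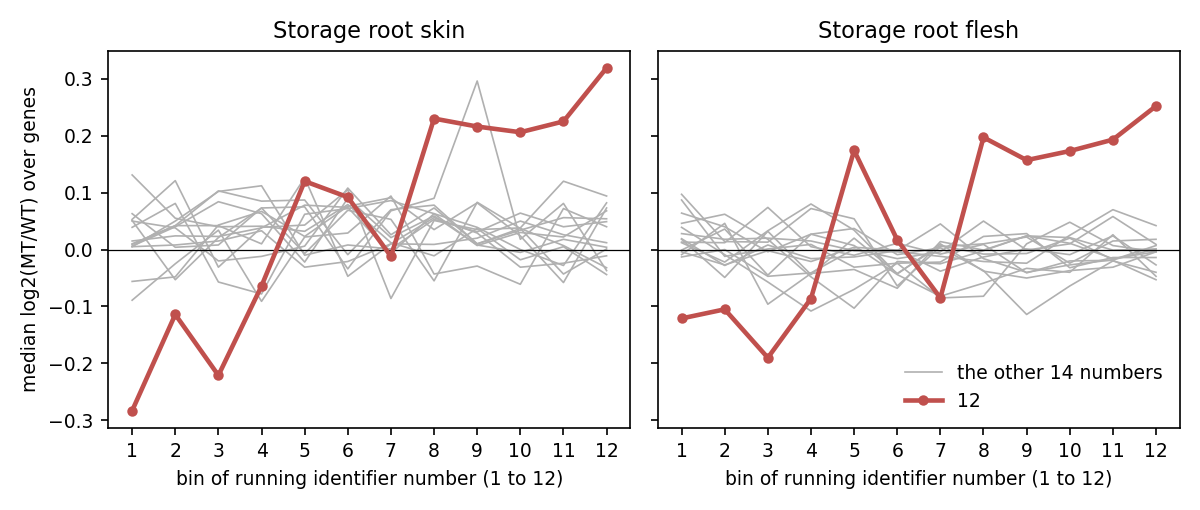
Median log2 ratio of MT to WT over genes in 12 bins of the running number within each haplotype block, for skin at left and flesh at right, with number 12 in red and the other 14 numbers in grey. Number 12 goes from -0.28 in the first bin to 0.32 in the last in skin and from -0.12 to 0.25 in flesh; the grey peak of 0.30 in skin is bin 9 of number 02, which holds 35 genes and is at -0.03 in flesh, and number 12 itself dips to -0.01 and -0.09 in bin 7.

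Skin against flesh showed how the tissues differ within each line. In WT, Ibat.Brg_v3.04DG012830 stood at 4080 CPM ± 291 in skin (SD, n = 3) and had 0 counts in flesh, at least 86800-fold higher, and Ibat.Brg_v3.07DG006890 at 1120 CPM ± 103, at least 23700-fold higher. Flesh genes were less abundant: Ibat.Brg_v3.10CG018600 stood at 376 CPM ± 12.4 and Ibat.Brg_v3.14FG019130 at 282 CPM ± 4.35 in WT flesh, with 0 counts in WT skin, at least 3940-fold and 2960-fold lower there. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 4.3e-15, 2.5e-13, 2.1e-12 and 3.3e-11 in that order. In WT 40463 genes differed, 21127 higher and 19336 lower in skin, or 52.2% higher. With library totals alone 17170 were higher and 26348 lower, 39.5% higher, and the median of all genes moved to -0.355 on the log2 scale, so the balance of directions between tissues rests on the scaling.

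In MT the same contrast gave 40732 genes, 20517 higher and 20215 lower in skin, 50.4% higher, or 39.8% with library totals alone, which put the median of all genes at -0.336. Ibat.Brg_v3.09EG019170 stood at 953 CPM ± 21 in MT skin with 0 counts in MT flesh (SD, n = 3), at least 17700-fold higher. Ibat.Brg_v3.04DG012830 had 2 counts over the MT flesh libraries, all in replicate 2, and 3440 CPM ± 89.7 in MT skin, a ratio of 95500 with an exact Poisson interval of 26400 to 789000; without replicate 2 the group is at 0 counts and only a bound remains. Ibat.Brg_v3.10AG018730 and Ibat.Brg_v3.01EG040860 had 0 counts in skin of both lines and stood at 155 CPM ± 1.63 and 39.8 CPM ± 1.27 in MT flesh, at least 1330-fold and 341-fold lower in skin. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, these 4 genes had adjusted p of 4.9e-13, 6.9e-15, 2.6e-12 and 6.4e-10.

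The tissue differences were largely shared between the lines. There were 16877 genes higher in skin in both lines, where independent lists would share 5390, and 15023 lower in both, against 4860, while 351 went in opposite directions. Of those shared, 52.9% were higher in skin, and 40.4% with library totals alone. Across genes, the tissue difference in WT and in MT had a correlation of 0.899, and genes are not independent replicates. At least 4-fold apart in both lines were 9436 genes higher in skin and 6096 higher in flesh. Genes above 10 CPM in a tissue of both lines with at most 3 counts over the 6 libraries of the other numbered 460 for skin and 73 for flesh; flesh libraries were deeper, which makes absence from flesh the stricter condition.

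The interaction asks whether the genotype difference itself differed between skin and flesh. It passed the test for 3653 genes, with 1177 higher and 2476 lower in skin relative to flesh. Among the 3211 of these genes with a mean log2 CPM of at least 1, Ibat.Brg_v3.01CG006240 and Ibat.Brg_v3.01EG003800 had the largest falls. These genes were absent from WT flesh, while in skin they rose by a log2 fold change of 0.42 and 0.65. The largest rises among the 3211 were those of Ibat.Brg_v3.06BG026240 and Ibat.Brg_v3.14AG019360, each with 0 counts in WT skin. In MT skin 06BG026240 had 1, 21 and 20 counts, and 14AG019360 had 16, 13 and 0 counts, so these rest on few reads. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p of the interaction was 1.1e-11, 5.3e-11, 0.0093 and 0.0087 in that order. Of the 3653 genes, 1185 passed the genotype test in flesh alone, 1420 in skin alone, 326 in both in the same direction, 327 in both in opposite directions and 395 in neither. Among the 2476 lower genes 1116 were skin-preferring and 546 flesh-preferring, and among the 1177 higher genes 408 and 255. DESeq2 called 5628 genes for the interaction.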

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

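The tests of skin and flesh tissue in the samples, of tissue classes, of depth or scaling and of genes numbered 12 were chosen after the results were seen; the exchanges of sample labels were planned before.

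The genotype difference was not the same in skin and in flesh for 3653 genes, by the interaction in edgeR's quasi-likelihood test. In 60 exchanges of genotype within tissues, drawn from 200 and counting the real one, 1 gave as many genes, the real one, and the highest other gave 1208; a chance division of the libraries is excluded at that share. These exchanges remove the genotype effect as a whole, so they do not show that it differs between the tissues, which rests on the interaction test alone. The 9 exchanges with the real genotype in a single tissue gave 225 to 1208 genes, the 3 that swapped it whole in a tissue and mixed it in the other gave 237 to 298, and the 47 that mixed it in both gave at most 1. None of those drawn swapped it whole in a tissue and left it real in the other. The count of genes changed in the same direction in both tissues, 1076, was likewise reached by 1 of the 60, with 1 gene in the highest other. Among 10 splits of 6 libraries, 1 reached each real count: 5502 genes in skin (highest other 2), 3985 in flesh (2), 40463 for the tissues in WT (0) and 40732 in MT (1). With 10 splits a share under 0.05 cannot be reached.

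Among the named genes, these differed between the tissues in their genotype effect, given as the log2 fold change in skin minus that in flesh. For genes with groups at 0 counts this difference is no bound. There it depends on the default prior count of edgeR's fit, not on the 2 used for log2 CPM. It was 4.01 for Ibat.Brg_v3.06DG004730 and -6.32 for Ibat.Brg_v3.12AG028750, both changed in skin. It was -13.93 for Ibat.Brg_v3.01CG006240 and -12.89 for Ibat.Brg_v3.01EG003800, both absent from WT flesh. Ibat.Brg_v3.08AG015460, lower in MT in both tissues, had 1.33, and Ibat.Brg_v3.06BG026240 and Ibat.Brg_v3.14AG019360 had 8.35 and 8.01. Of the genes named for the tissue contrast, Ibat.Brg_v3.07DG006890 had -7.80, with 1.96 CPM ± 0.767 in MT flesh against 0 counts in WT flesh, and Ibat.Brg_v3.10CG018600 had 7.42, with 0.978 CPM ± 0.781 in MT skin against 0 counts in WT skin (SD, n = 3).

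Skin-preferring genes made up 53.5% of the rises in MT flesh, and 43.3% with classes from the MT libraries alone. This lean was not particular to flesh. Among the rises in MT skin their odds ratio was 2.51, or 2.06 with classes from WT alone. Among the falls in MT skin it was 1.13, or 1.61 with classes from WT alone and 0.795 from MT alone. With WT classes, calls in skin thus leaned to skin-preferring genes in both directions. Of the 3016 rises in MT flesh, 887 were also called higher in MT skin. Whole skin carried into the MT flesh samples would bring all abundant skin transcripts. Yet the 145 genes limited to skin in WT reached a median of 0.059% of their skin level, and the 10 most abundant of them at most 3.23%. The skin-preferring rises in MT flesh needed a median of 12.6% (quartiles 5.31% and 25.2%), though 48 of the 145 were higher in MT flesh by the test. These values argue only against skin carried over whole. A part of the skin with little of these 145 transcripts could have been carried over unseen. Depth or scaling fell short, since the odds ratio for the flesh rises was 3.74 in libraries thinned to the smallest total and 4.63 with library totals alone. Genes numbered 12 fell short too, since it was 4.55 without them. With all genes kept and classes from the MT libraries alone, the odds ratio was 2.64. A candidate explanation is that the mutant expresses part of the skin programme in its flesh, a hypothesis drawn from these same data and not tested directly here. Measuring these transcripts in separated layers of the flesh would test it.

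Flesh-preferring genes were not enriched among the rises in MT skin, with 521 of them or 17.8% against 23.5% of the other tested genes. With classes from the WT libraries alone the shares were 22.9% and 22.8% (odds ratio 1). A change in MT does not move those classes, but the WT skin libraries enter both the classes and the contrast. The 33 genes limited to flesh in WT stood in MT skin at a median of 0.556% of their flesh level (quartiles 0.412% and 0.921%), where the rises needed a median of 14% (lower quartile 7.22%), which argues against flesh tissue as their whole cause. These genes were chosen for their low level in WT skin, so the lines cannot be compared by them. What raised these genes stays open.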

How the results depend on the processing

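The alternatives with library totals alone, thinned libraries or genes numbered 12 left out, and all those on the step along number 12, the skin-preferring rises (including classes from a single line) and the tissue calls shared by both lines, were chosen after seeing the data, as were other count filters, the surrogate factor and fits of only the groups compared for the genes changed in both tissues. The 20 named results kept their direction and their side of the threshold under every alternative that gave them a value, including 144 with a library left out. With an absolute log2 fold change of at least 1, 2314 genes differed in skin, 2059 in flesh, 2259 in the interaction and 273 in both tissues, by construction fewer. DESeq2 called 8191 genes in skin, 5880 in flesh and 5628 for the interaction, and the cause was not tested. Without a low-count filter 7348 genes differed in skin and 5665 in flesh, and with a minimum count of 30 these were 5898 and 4260. RLE scaling gave 5607 and 3995, and a surrogate factor 5496 and 4027. Fits of only the groups compared gave 4255 in skin and 5478 in flesh. Of the 4255, 3508 were also called in the main fit. With a limit of 3 counts in place of 1, 28 genes were lost or gained in MT, by construction more than 17. Leaving out each library gave 3583 to 4490 genes in skin, the lowest without WT skin replicate 2, 2827 to 2978 in flesh, 36983 to 38300 and 37001 to 39322 between tissues in WT and MT, 2696 to 3356 for the interaction and 812 to 930 in both tissues. It gave 29790 to 31329 tissue calls shared by the lines, an odds ratio of 4.6 to 5.08 for skin-preferring rises, and a step along number 12 of 0.242 to 0.261; without haplotype F that step was 0.328.

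Same-numbered libraries of different groups had correlations from -0.017 to 0.015 in their deviations from the group means. Of 12 libraries, 5 correlated best with their own number. No shared signal by number was seen, which cannot tell whether skin and flesh came from the same roots. With a replicate block the counts were 4326 in skin, 3420 in flesh, 39027 and 39214 between tissues, 2950 for the interaction and 912 in both tissues. Flesh calls were 75.7% higher, 58.6% with library totals alone and 65.4% with only the groups compared in the fit. Thinned to the smallest total, 5345 genes differed in skin and 3492 in flesh. The planned gene lists, with their alternatives, and the runs of neighbouring genes by coordinates were not run, because the identifiers carry no names or coordinates in the sources used here. Depth limits absence: in the shallowest library 3 counts stand for 0.397 CPM.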

Other observations

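The tests of the step along number 12 and the tests by identifier number in this part were chosen after the results were seen.

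Skin- and flesh-preferring genes were not spread evenly over the identifier numbers. Of tested genes numbered 14, 18% were skin-preferring (odds ratio 0.722, adjusted p = 2.3e-15 over 15 numbers, Fisher's exact test) and 26.9% flesh-preferring (odds ratio 1.23, adjusted p = 1.3e-07). Number 08 leaned the same way, with 20.6% skin-preferring (odds ratio 0.862, adjusted p = 0.0021) and 27.1% flesh-preferring (odds ratio 1.24, adjusted p = 3.7e-07), by Fisher's exact test. Numbers 07 and 13 leaned to skin, each with 25.1% skin-preferring and an odds ratio of 1.13 (adjusted p = 0.0021 and 0.003, Fisher's exact test), and numbers 04 and 11 held fewer flesh-preferring genes, 22% and 21.5% (adjusted p = 0.037 and 0.017). Number 12 did not pass this test in either class, with 23.9% skin-preferring and 22.3% flesh-preferring. Genes on several haplotypes can be copies of a single gene, so these p-values are too small.

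The summed CPM of haplotype F on number 12 stood apart from the other letters. Relative to all other numbered genes, its second part was 1.31-fold higher in MT flesh and 1.4-fold in MT skin (134 genes), and its first part 1.09-fold in each. On haplotypes A to E the first part fell to 0.894-fold in flesh and 0.844-fold in skin, and the second rose to 1.12-fold in each. In every case all 3 MT libraries lay beyond all 3 WT libraries of the tissue, which chance gives in 10% of splits.

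A step along the identifiers numbered 12 was seen in both tissues. The values argue against a chance run of genes, since the same search on the other 14 numbers gave at most 0.042 in flesh against 0.219, and against depth or scaling, since the step was 0.249 with library totals alone and 0.257 in thinned libraries. A candidate explanation is a change in copy number, with 1 copy of 6 lost for the first part and 1 gained for the second; genes lost from MT in both tissues lay in the first part with an odds ratio of 8.53, but all genes lower in both tissues lean there too (82 of 2671 tested against 12 of 3490), so this restates the step and gives copy loss no separate support. For the first part 5 copies of 6 would give -0.26. The summed log2 change over haplotypes A to F was -0.09 ± 0.004 in skin, where the split was found, and -0.04 ± 0.011 in flesh (SE). For the second part 7 of 6 would give 0.22, and the change was 0.21 ± 0.004 in skin and 0.20 ± 0.005 in flesh. Haplotype F splits at 25540 and the others between 7270 and 12020, so by running number each sum over A to F mixes unlike segments. Haplotype F held 390 of the 942 genes summed for the first part and 134 of the 1334 for the second. Neither the near match of the second part nor the miss of the first therefore weighs for or against the copy ratios. Over A to E alone the first part changed by -0.24 ± 0.007 in skin and -0.16 ± 0.015 in flesh. The second part changed by 0.16 ± 0.003 and 0.17 ± 0.006. The sums over A to E leave out 1 haplotype, so the ratios for 6 copies do not apply to them. Expression need not follow copies and reads may be divided unevenly among haplotypes. A copy change therefore cannot be told apart from a change in regulation without DNA measurements, which were not analysed here.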
